A study of Homo sapiens with 6 samples.

How the data were processed

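Total RNA of SiHa cells was extracted with TRIzol, labelled with Cyanine 3 and hybridised to 1-colour Agilent human miRNA arrays, per the labels' protocols. The dose of curcumin is not given in the sources used here. The arrays were scanned and read with Agilent Feature Extraction 11.5.1.1, per the file headers. For each spot the authors deposited the background-subtracted intensity on a linear scale, not normalized between arrays, together with mean and background intensities and flags for detection, outliers and saturation. They also deposited a value table of the whole series, whose values are intensities on a linear scale, neither centred nor scaled between arrays. Set against the scanner files, it held the total gene signal of the same arrays, within 1% for all miRNAs but at most 1 on every array, with a median of 0.1 in each column, the value given to a miRNA that was not detected. It has no direction, since each column is 1 array.

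Control spots and spots marked as outliers were left out (3.00% to 3.76% of the spots of an array), and 0 spots were saturated. Between 46.0% and 53.0% of spots had a background-subtracted intensity of 0 or less. Spots of a probe were averaged on the linear scale. A probe was taken as detected on an array when more than 0.5 of its spots were well above background by the scanner's own flag. Each array was divided by its 75th percentile over the 140 probes detected on all 6 arrays, floored at the median over arrays of the lowest scaled signal of a detected probe (-4.31 in log2) and brought to the log2 scale, so a value at the floor understates the difference of a dim miRNA. The value of a miRNA was the mean over its probes detected on every array of at least 1 group. Of the human miRNAs on the array 138 were tested: 91 detected on all 6 arrays, 38 detected on all DMSO arrays and fewer curcumin arrays, and 9 the other way round. Of these, 80 had more than 1 probe, and in 17 the probes disagreed in the sign of the fold change, among them hsa-let-7a-5p, hsa-miR-15b-5p and hsa-miR-494-3p. Names of miRNAs are those of the array design.

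Curcumin (3 arrays) was compared with DMSO (3 arrays) with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 138 miRNAs and a threshold of 0.05. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. On simulated data of this comparison with 20 of 138 miRNAs changed in each of 20 draws, a log2 change of 1 was recovered for 28.75% of changed miRNAs, one of 2 for 86% and one of 3 for 97.25%, with 0.45 to 1.2 false calls per draw. A simulated list of 10 shifted miRNAs was called in 20 of 20 draws and an unshifted list in 0. The simulated miRNAs were independent of each other, while the correlation estimated within the tested lists ran from 0.39 to 0.98. The simulated rates therefore need not hold for the real arrays. The number of arrays limits the precision of every value.

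The 20 lists of miRNAs were written from general knowledge before the data were examined, as were the tests and the rule for named miRNAs. Lists with at least 3 tested members were tested with camera of limma (preset correlation 0.01, and again with an estimated correlation) and with fry, which tests whether members move one way on balance and does not compare them with other miRNAs. Counts of miRNAs per array, total signal and the share of the 10 brightest miRNAs were compared with exact permutation tests. The arms of a hairpin were compared by exact permutation over all 40320 pairings, in place of the random resamples first planned. The named miRNAs are the 12 highest and 12 lowest fold changes among those that pass, are detected on all 6 arrays and do not overlap, or, where fewer pass, those that pass and as many of smallest p as make 5 per direction, then miRNAs detected on all arrays of 1 group and none of the other, for each list the brightest member and the 3 of smallest p, the 5 brightest miRNAs, and 8 miRNAs fixed by name. A miRNA not well above background on any array of a group was to be given as a bound, the mean of the brighter group against the higher of the detection limit and its own signal in the dimmer group. Others are named as chosen after their values were seen.

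The alternatives were normexp background correction with an offset of 50, the 75th percentile over all probes, quantile normalization, cyclic loess, no scaling, the series value table, the total gene signal, the brightest probe, all probes, no filter, detection on all 6 arrays, a floor 10 times lower, outlier-marked spots kept, a variance trend, the replicate number as a block, removal of each array's linear trend with probe GC content, each array left out, and a 2-fold threshold. Slide and scan could not be fitted as a block, since each group lay on a slide of its own. A RefSeq gene table of assembly GRCh38.p14 was used only to tell which miRNA hairpins neighbour each other, and no coordinate from it is given.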

Results

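The series profiled microRNAs (miRNAs) in SiHa cells, an established human cervical cancer line that carries HPV16, 24 h after curcumin, the yellow polyphenol of turmeric, was added. Cells given the DMSO vehicle at 0.4% served as the control. Each group held 3 arrays. Between 102 and 218 miRNAs were detected per array, and 138 miRNAs, detected on every array of at least 1 group, entered the comparison. The question was which miRNAs differ in level between curcumin-treated and vehicle-treated cells at this time point.

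No miRNA passed the test for a difference between curcumin and DMSO. The smallest p in each direction belonged to hsa-miR-181a-5p, a miRNA of lymphocyte development, with a log2 fold change of 1.04 ± 0.27 (SE, 95% interval 0.42 to 1.66), and to hsa-miR-125a-3p at -0.78 ± 0.26. hsa-miR-23a-3p at 0.81 ± 0.29, hsa-miR-30a-5p at 0.82 ± 0.30, hsa-miR-29a-3p at 0.87 ± 0.36 and hsa-miR-1260b at 1.26 ± 0.45 followed among miRNAs with a positive fold change. Among those with a negative one came hsa-miR-324-3p at -0.71 ± 0.28, the hypoxia-induced hsa-miR-210-3p at -0.57 ± 0.24, hsa-miR-130b-3p at -0.75 ± 0.37 and hsa-miR-21-3p at -0.51 ± 0.25. These 10 miRNAs, the 5 of smallest p in each direction, all had a limma adjusted p of 0.526 and none is a called change. Without curcumin replicate 1, with probes chosen anew, hsa-miR-181a-5p stood at 0.44, hsa-miR-1260b at 0.63 and hsa-miR-29a-3p at 0.55. For hsa-miR-181a-5p the choice of probes had a large part in such a drop. Without DMSO replicate 2 and curcumin replicate 1 it stood at 0.39 with probes chosen anew. With the probes and scaling of the 6-array comparison it stood at 0.93 without the same arrays.

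In single arrays, hsa-miR-181a-5p lay at -3.10 ± 0.13 log2 scaled signal (SD, n = 3) after DMSO and at -2.05 ± 0.32 after curcumin, with no overlap between the groups. hsa-miR-210-3p lay at -2.74 ± 0.05 and -3.31 ± 0.10, also without overlap. hsa-miR-29a-3p lay at 0.04 ± 0.62 and 0.91 ± 0.30, and its groups overlapped. hsa-miR-125a-3p, hsa-miR-324-3p and hsa-miR-130b-3p were detected on 3 of 3 DMSO arrays and on 2 of 3 curcumin arrays. The groups did not overlap for 19 of the 138 miRNAs (13.8%), where chance gives 10%. On hg19, the build in the file headers, the array lists the probes of hsa-miR-23a-3p at chromosome 19, 13947449 to 13947465, those of hsa-miR-29a-3p at chromosome 7, 130561550 to 130561568, those of hsa-miR-30a-5p at chromosome 6, 72113266 to 72113280, and those of hsa-miR-210-3p at chromosome 11, 568161 to 568175. The files do not say which of these lie in introns or exons.

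**Figure D1:**
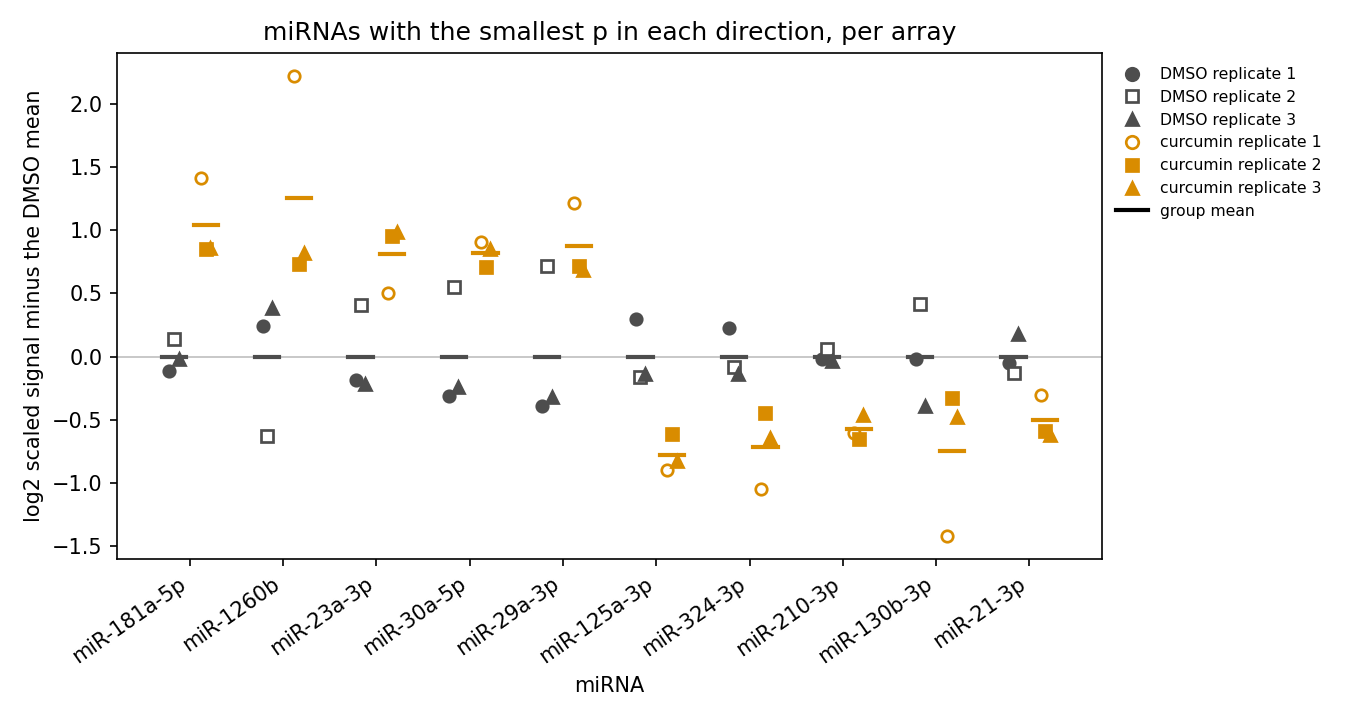
Values per array of the 10 miRNAs with the smallest p in each direction, as log2 scaled signal minus the DMSO mean of the same miRNA (vertical axis), for the miRNAs on the horizontal axis. Points are arrays, bars are group means (n = 3), and open points mark DMSO replicate 2 and curcumin replicate 1. The mean for hsa-miR-181a-5p after curcumin lies 1.04 above the DMSO mean and that for hsa-miR-125a-3p lies at -0.78, and none of the 10 passed the test.

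By limma's test with Benjamini-Hochberg adjustment, 0 miRNAs were higher and 0 were lower at an adjusted p under 0.05, and 10 of 138 had an unadjusted p under 0.05 (7 higher, 3 lower, against 6.9 expected by chance). Log2 fold changes ran from -1.21 to 1.34. The 95% interval of a miRNA had a median half-width of 0.73 log2 units (1.66-fold), and for 58 miRNAs it lay within 2-fold in either direction. This count was taken over all 138 miRNAs, those with values at the floor as well. For such a miRNA the fold is understated, so its interval does not exclude a change of 2-fold or more. All DMSO arrays were on slide 1 and all curcumin arrays on slide 2, each scanned apart, so that slide, scan and treatment cannot be told apart. With DMSO replicate 2 and curcumin replicate 1 left out, a choice made after the data were seen, limma called 28 miRNAs higher and 38 lower of 164 (38 higher and 24 lower of 138 with the probes and scaling of the 6-array comparison), and with array quality weights, also chosen afterwards, 31 higher and 19 lower of 138. Leaving out or weighting down the arrays farthest from their groups lowers the spread that the test uses. The p-values behind these counts are therefore likely too small.

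The groups of related miRNAs were next. All 3 members of the miR-29 family, whose known targets are collagens and DNA methyltransferases, had positive fold changes, with a median of 0.87, and hsa-miR-29b-3p stood at 1.34 ± 0.59 and hsa-miR-29c-3p at 0.68 ± 0.45, the last detected on 1 of 3 DMSO arrays and 3 of 3 curcumin arrays. All 5 members of the miR-23/24/27 clusters had positive values too (median 0.51), among them hsa-miR-23b-3p at 0.61 ± 0.30, hsa-miR-27a-3p at 0.51 ± 0.47 and hsa-miR-24-3p at 0.14 ± 0.27. Of 12 tested members of the list of miRNAs that earlier reports tied to curcumin, 10 were above 0 (median 0.26). They included hsa-miR-22-3p at 0.77 ± 0.33 and hsa-miR-221-3p, which represses a cyclin-dependent kinase inhibitor, at 0.65 ± 0.28 with detection on 1 of 3 DMSO arrays and 3 of 3 curcumin arrays. All 12 tested miRNAs of the list of GC-rich array miRNAs were below 0 (median -0.23, and 11 of 12 with normexp background correction), with hsa-miR-4459 at -0.88 ± 0.56, hsa-miR-6869-5p at -0.76 ± 0.43, hsa-miR-1268b at -0.58 ± 0.32 and hsa-miR-6165 at -0.17 ± 0.30. Detection on all arrays of 1 group was enough for a miRNA to be tested, which can favour a fold change toward that group. Of the GC-rich list 5 members were detected on all 6 arrays, and with detection on all 6 arrays its median was -0.14. None of these 4 lists passed: camera with a preset correlation of 0.01 gave each an adjusted p of 0.0613, and with an estimated correlation the adjusted p was 0.711 for each. Without DMSO replicate 2 all 4 passed by the preset correlation, and with an estimated correlation the adjusted p was 0.364 for each. Across the 138 miRNAs, which are not independent replicates, the fold change correlated with the GC content of the probes at r = -0.414, and at r = -0.643 without DMSO replicate 2. After removal of each array's GC trend the median of the GC-rich list was 0.078. The removal raises GC-rich miRNAs by construction here, and it would also take out an effect of curcumin tied to GC content.

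The let-7 family, known repressors of RAS and HMGA2, had 3 members above 0 and 5 below (median -0.10, camera adjusted p = 0.355), with hsa-let-7b-5p at -0.33 ± 0.26, hsa-let-7e-5p at -0.58 ± 0.32 and hsa-let-7c-5p at 0.10 ± 0.27. After removal of each array's GC trend 0 of its members were above 0 and 8 below (median -0.36, camera adjusted p = 0.0241, unadjusted p = 0.107 with an estimated correlation and adjusted p = 0.522). The probes of these members had a low GC content (31.7% to 45.9%). Removal of a trend that falls with GC content lowers such miRNAs, so the direction of this move follows from the removal. The cluster of hsa-miR-17-5p and hsa-miR-92a-3p with its paralogs, a target of MYC, had 6 above 0 and 3 below (median 0.12, adjusted p = 0.239), with hsa-miR-25-3p at 0.69 ± 0.33, hsa-miR-19a-3p at 0.50 ± 0.45, hsa-miR-93-5p at 0.41 ± 0.27 and hsa-miR-19b-3p at -0.08 ± 0.32. The miR-15/16 family had 3 of 3 above 0 (median 0.14, adjusted p = 0.540), with hsa-miR-16-5p at 0.21 ± 0.29 (-0.018 with quantile normalization), hsa-miR-15a-5p at 0.14 ± 0.43 and hsa-miR-15b-5p at 0.08 ± 0.36 (-0.028 with the series value table). In the oncogenic list 7 of 10 were above 0 (median 0.41, adjusted p = 0.266), and in the list of HPV and cervical cancer miRNAs 11 of 14 (median 0.16, adjusted p = 0.223), where hsa-miR-378a-3p stood at -0.36 ± 0.25. The miRNAs that target NRF2 or KEAP1 had 3 of 3 above 0 (median 0.41, adjusted p = 0.266), with hsa-miR-7-5p at 0.11 ± 0.38. Camera with an estimated correlation gave an adjusted p of 0.711 for each of the 11 lists it could test, and fry one of 0.706.

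Of 11 tested miRNA entries that overlap other abundant RNAs, such as pieces of tRNA, 7 were above 0 (median 0.37, camera adjusted p = 0.349). Among them were hsa-miR-1260a at 0.94 ± 0.46 and hsa-miR-1273g-3p at 0.70 ± 0.36. Without DMSO replicate 2 and curcumin replicate 1 the median of this list was -0.30. Lists with fewer than 3 tested members had no list test. The p53-induced miRNAs were represented by hsa-miR-34a-5p at 0.50 ± 0.48 and hsa-miR-107 at 0.22 ± 0.27, the miR-181 family by hsa-miR-181a-5p and hsa-miR-181b-5p, the latter at 0.32 ± 0.43, the miR-30 family by hsa-miR-30a-5p and the 14q32 cluster by hsa-miR-494-3p at -0.05 ± 0.63. In each list 0 members passed over all 138 miRNAs. With p adjusted over the list alone, 1 of 1 passed in the miR-30 family and 1 of 2 in the miR-181 family, hsa-miR-30a-5p and hsa-miR-181a-5p, and 0 in each of the other lists. With 1 tested member there is nothing to adjust for, so hsa-miR-30a-5p only keeps its unadjusted limma p of 0.0247.

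The values of named miRNAs and lists moved when single arrays were left out. Of 44 named miRNAs, 33 moved by more than 1.5 times or changed sign without 1 of the arrays. Probes and scaling were chosen anew each time, so part of a move can come from them, as for hsa-miR-181a-5p. Without curcumin replicate 1, hsa-miR-1260a stood at 0.36, hsa-miR-4459 at -0.41, hsa-miR-29b-3p at 0.70, hsa-miR-29c-3p at 0.28, hsa-miR-27a-3p at 0.037, hsa-miR-25-3p at 0.37, hsa-miR-22-3p at 0.42, hsa-miR-21-5p at 0.15 and hsa-miR-34a-5p at -0.059. For the miR-29 family the median was 0.55 without curcumin replicate 1 and 1.23 without DMSO replicate 2. For the miR-23/24/27 clusters it was 0.072 without curcumin replicate 1, 0.23 without DMSO replicate 3, 0.25 without DMSO replicate 1 and 0.78 without DMSO replicate 2. For the curcumin miRNAs of earlier reports it was -0.064, 0.081, 0.047 and 0.52 in the same order, for the oncogenic list 0.15, 0.25, 0.19 and 0.56, and for the list of NRF2 and KEAP1 targeting miRNAs 0.037, 0.23, 0.25 and 0.56. For the list of hsa-miR-17-5p and its paralogs the values in that order were -0.036, -0.048, 0.028 and 0.34. The list of HPV and cervical cancer miRNAs stood at 0.11, 0.029, 0.037 and 0.43, the miR-15/16 family at 0.11, -0.043, -0.099 and 0.43, the let-7 family at -0.24, -0.29, -0.31 and 0.23, and the GC-rich list at -0.34, -0.16, -0.095 and -0.42. The entries that overlap other abundant RNAs stood at 0.020 without curcumin replicate 1 and 0.012 without DMSO replicate 2.

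**Figure D2:**
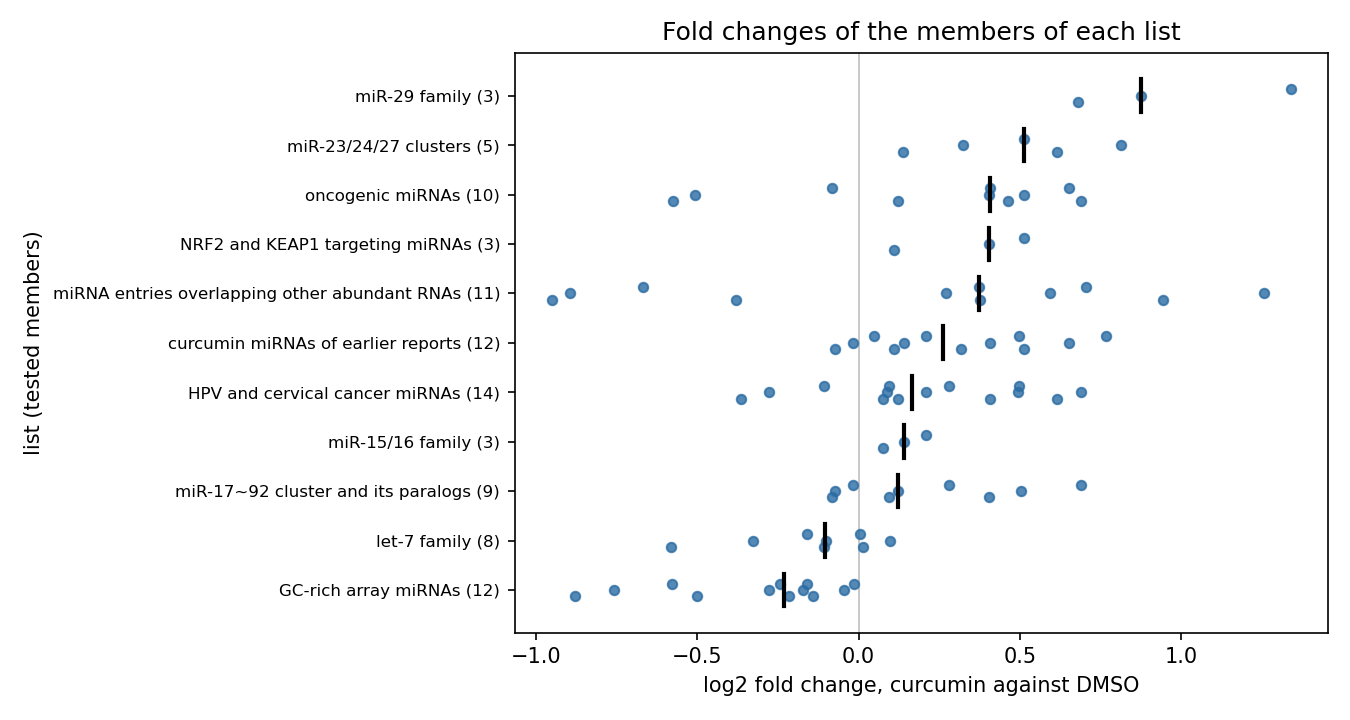
Log2 fold change of curcumin against DMSO (horizontal axis) for each tested member of the 11 lists with 3 or more tested members (vertical axis, number of members in parentheses). Points are miRNAs and vertical bars list medians, which run from -0.23 for the GC-rich array miRNAs to 0.87 for the miR-29 family.

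The miRNAs most studied in cervical cells and the brightest ones gave these values. hsa-miR-21-5p, an oncogenic miRNA, stood at 0.41 ± 0.31, and hsa-let-7a-5p at -0.10 ± 0.32. The 5 brightest miRNAs were hsa-miR-7975 at 0.27 ± 0.37, hsa-miR-7977 at 0.38 ± 0.37, hsa-let-7b-5p, hsa-let-7a-5p and hsa-miR-5100 at 0.37 ± 0.34. Of these, hsa-miR-7975, hsa-miR-7977 and hsa-miR-5100 are on the list of entries that overlap other abundant RNAs. Their signal need not come from miRNAs. hsa-miR-7975 alone held between 23.9% and 40.7% of the probe signal of an array. hsa-miR-203a-3p, hsa-miR-200c-3p and hsa-miR-145-5p were not well above background on any of the 6 arrays. The same held for all 5 members of the epithelial miR-200 family and for the 25 members on the array of the C19MC placental cluster. It held as well for 9 blood cell miRNAs and 8 fibroblast and muscle miRNAs, as markers of other cell types. Of 9 endothelial, liver and neural miRNAs, 3 (hsa-miR-126-3p, hsa-miR-9-3p and hsa-miR-128-3p) were detected on some arrays and 0 could be tested. hsa-miR-3196 was detected on 3 DMSO arrays and 0 curcumin arrays, but so close to the limit of detection that no bound on a fold could be given (limma adjusted p = 0.763).

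The opposite arms of one hairpin were both tested for 8 miRNAs. Detection on all arrays of 1 group was enough for an arm to be tested, which can favour a fold change toward that group. With detection on all 6 arrays 2 hairpins were left. In 8 of 8 the fold change of the 5p arm was above that of the 3p arm, as in miR-21 (5p at 0.41, 3p at -0.51), miR-30a (0.82 and -0.45) and miR-324 (0.17 and -0.71), and the arms had the same sign in 3. Without curcumin replicate 1 the fold change of the 5p arm was above in 7 of 9 hairpins, and without both this array and DMSO replicate 2 also in 7 of 9. Across these 8 hairpins, which are not independent replicates, Pearson's r between the fold changes of both arms was 0.716 (exact permutation p = 0.0532, adjusted p = 0.106, two-sided) and Spearman's rho 0.548 (exact permutation p = 0.171, adjusted p = 0.171). Without the 2 hairpins farthest from the median r was 0.516. Without curcumin replicate 1 it was -0.150 over 9 hairpins (exact permutation p = 0.70), and without DMSO replicate 2, curcumin replicate 2 or curcumin replicate 3 it was 0.797, 0.842 and 0.840 (exact permutation p = 0.0237, 0.0158 and 0.0186).

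The arrays themselves differed. DMSO replicates 1, 2 and 3 detected 140, 218 and 136 miRNAs and curcumin replicates 1, 2 and 3 detected 102, 163 and 166, a mean of 165 ± 46.2 (SD, n = 3) against 144 ± 36.1 (exact permutation p = 0.6, two-sided, adjusted p = 0.9 over 3 such measures, smallest possible p 0.1). The sign of this difference in detected miRNAs per array turned without DMSO replicate 2 (5.67 more miRNAs after curcumin). The total probe signal was 186404 ± 100427 intensity units against 165057 ± 40130 (exact permutation p = 0.8), and the 10 brightest miRNAs took 74.7 ± 5.40% against 75.2 ± 1.80% of it (exact permutation p = 0.9). DMSO replicate 1 and DMSO replicate 3 correlated at r = 0.990 across miRNAs and curcumin replicate 2 and curcumin replicate 3 at r = 0.995. DMSO replicate 2 correlated with its own group at a mean r of 0.898 and curcumin replicate 1 with its own at 0.899.

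**Figure D3:**
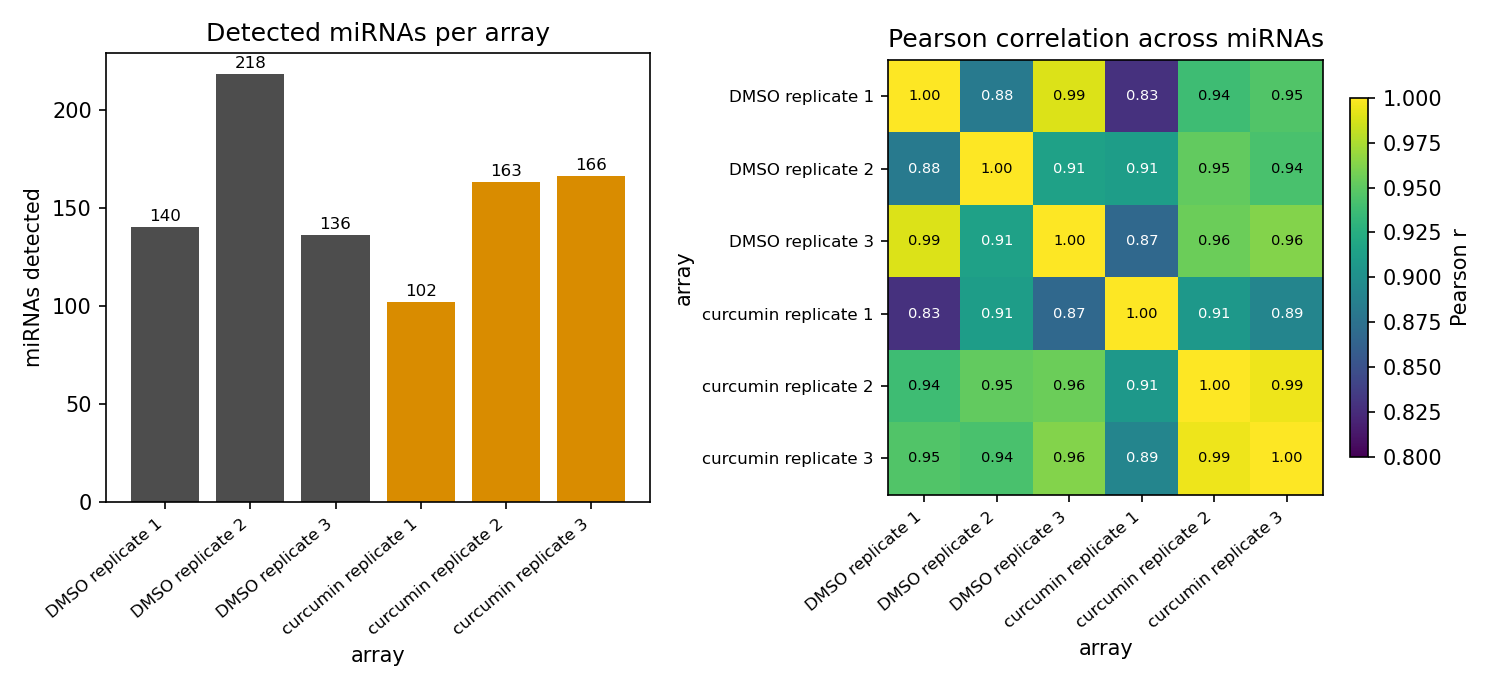
Left, number of miRNAs detected (vertical axis) on each array, from 102 on curcumin replicate 1 to 218 on DMSO replicate 2. Right, Pearson correlation across the 138 miRNAs between all pairs of arrays, in which DMSO replicate 2 and curcumin replicate 1 correlate less with their own groups (means 0.898 and 0.899) than the remaining pairs do (0.990 and 0.995).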

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

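The swap of arrays, the GC test of each array alone and the GC correlation without single arrays were chosen only after the result was seen. Some of the spike-in RNAs, added to every sample in the laboratory and outside the comparison of miRNAs, differed between the groups. The spike-in dmr_285, used to follow labelling, was 2.31 times as bright on curcumin arrays (3548 ± 507 intensity units, SD, n = 3) as on DMSO arrays (1546 ± 342), and dmr_6, used to follow hybridisation, 2.69 times (361 ± 36.5 against 135 ± 21.4). Every curcumin array lay above every DMSO array for both (exact permutation p = 0.1, the smallest possible, adjusted p = 0.2 over 4 spike-ins). The remaining spike-ins, dmr_31a and dmr_3, stood at 1.17 and 1.08 times with overlap between the groups. As dmr_31a is also used to follow labelling, a difference in labelling as a whole is not shown. The spike-ins do not come from the cells, so these values mark a technical difference between the arrays of both groups, in which slide, scan and handling were not separated.

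DMSO replicate 2 and curcumin replicate 1 stood apart from their groups: the SD over 138 miRNAs of the deviation from the other arrays of the group was 0.79 and 0.86 log2 units, while the remaining pairs differed with SDs of 0.25 and 0.19. A difference in total signal that acts on dim miRNAs would fade among bright ones, but over the brighter 69 miRNAs the smaller SD was 0.85. An effect of total signal that also reaches bright miRNAs stays open, since both arrays were the extremes of their groups. DMSO replicate 2 had a total probe signal of 302365 intensity units, against 127861 and 128986 for replicates 1 and 3. Curcumin replicate 1 had 119377, against 181161 and 194634 for replicates 2 and 3. A swap of these arrays is argued against by the correlation of curcumin replicate 1 with DMSO replicates 1 and 3, which lay below that with curcumin replicates 2 and 3 (difference -0.0511), although DMSO replicate 2 correlated better with curcumin replicates 2 and 3 (0.947) than with its own group (0.898), so a wrong label on that array alone stays open. Probe GC content is argued against for curcumin replicate 1, whose SD stayed at 0.84 after removal of the linear GC trend, and stays open for DMSO replicate 2, whose SD went from 0.79 to 0.48. Differences between separate cultures were not tested.

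Fold changes became lower with rising probe GC content (r = -0.414 across 138 miRNAs, permutation p = 1e-05, the smallest the permutations can give, and rho = -0.420). The permutation shuffled GC content over miRNAs, which are not independent replicates, so its p does not test curcumin against DMSO. Splits of the arrays that set DMSO replicates 1 and 3 with 1 curcumin array gave a stronger correlation (absolute r of 0.63, 0.69 and 0.68). The remaining mixed splits gave a weaker one (at most 0.39). DMSO replicate 2 as the source is argued against: its deviation from its group correlated with GC content (absolute r of 0.797), but with a sign that works against the trend, and without it the correlation was stronger (r = -0.643). Curcumin replicate 1 stays open as a part, since without it r was -0.341. With DMSO replicate 2 already left out, leaving out curcumin replicate 1 as well did not weaken the correlation (r = -0.643 without both arrays). With probes chosen anew, r without both arrays was -0.601. The GC slopes of the arrays, 0.07 ± 0.26 log2 units per 10% GC (SD, n = 3) for DMSO and -0.07 ± 0.06 for curcumin, gave an exact permutation p of 0.4. An effect of curcumin on GC-rich miRNAs was not separated from slide and scan.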

How the results depend on the processing

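The omission of both arrays that stand apart (with newly chosen probes or those of the 6-array comparison), array quality weights and spike-in scaling were chosen after the data were seen, as were the arm and detection values without single arrays. With limma, 0 miRNAs passed under any of the 24 alternatives chosen at the outset in either direction (counts at an unadjusted p under 0.05 from 0 to 40, smallest adjusted p from 0.0542 to 0.995). Without DMSO replicate 2, 40 miRNAs had an unadjusted p under 0.05 and the smallest adjusted p was 0.0542, and without curcumin replicate 1, 22 had one. With both arrays that stand apart left out 28 miRNAs were higher and 38 lower, with both arrays left out with the probes of the 6-array comparison 38 and 24, and with array quality weights 31 and 19. The cause was not tested further than by the values under the other headings. Fold changes of 44 named miRNAs were compared in 1178 cases: 1037 kept their sign and side of the threshold, 71 passed the threshold with the same sign and 70 changed sign. Of 295 such cases for list medians 226 stayed, 51 passed and 18 changed sign. Where arrays were left out the probes of a miRNA were chosen anew, so part of a move, as for hsa-miR-19b-3p, comes from an added or dropped probe. A miRNA close to background lies near the floor, which limits its fold.

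Camera with the preset correlation called 0 lists in the comparison as reported. It called 4 with normexp background correction, 2 with the 75th percentile over all probes, 1 with no scaling, 5 with the series value table, 5 with the total gene signal, 4 with all probes of the miRNA, 13 with no filter on dim probes, 1 with the replicate block (the miR-29 family, adjusted p = 0.00342, unadjusted p = 0.160 with an estimated correlation), 2 with the GC trend removed (the let-7 family, adjusted p = 0.0241, and the miR-29 family, adjusted p = 0.0489, with unadjusted p of 0.107 and 0.188 by an estimated correlation) and 1 with the GC trend removed and the replicate block. It called 2 with both arrays left out, 3 with both left out on the probes of the 6-array comparison, 3 with array quality weights, 2 with spike-in scaling, and 0 to 6 without single arrays (6 without DMSO replicate 2). With an estimated correlation 0 lists passed in any of these, except 8 with no filter, where most other miRNAs lie at the floor by construction. Fry called 0 lists in the comparison as reported, 3 without DMSO replicate 2, 1 with no filter on dim probes, 1 with both arrays left out, 8 with both left out on the probes of the 6-array comparison, 1 with array quality weights and 0 with each of the remaining alternatives. For the remaining calls the cause was not tested. Slide could not be a block.

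The difference in the number of detected miRNAs per array, -21, was -35.3 to 5.67 without single arrays and 26.5 without both (exact permutation p = 0.333). The correlation between opposite arms of one hairpin, 0.716, was -0.150 to 0.842 without single arrays and 0.00290 without both arrays. With detection on all 6 arrays 2 hairpins were left and no correlation could be had. The median over miRNAs moved by -0.58 with the 75th percentile over all probes, -0.19 with no scaling, -0.22 with the series value table, -0.23 with the total gene signal and -0.80 with spike-in scaling, and fold changes under these are given relative to that shift. Values at the floor hold this median back: with spike-in scaling, 1 factor per array, miRNAs above the floor moved by a median of -0.96, so a common offset of -0.16 remains in them, and the turns to negative values under it come from that offset alone and say nothing about single miRNAs or lists.

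Signs turned as follows. The turns to negative values with spike-in scaling come from the offset given above. With the GC trend removed, the direction of a move follows from the GC content of the probes. For the rest the cause was not tested. With the GC trend removed, with or without the replicate block, hsa-let-7c-5p turned to -0.13, hsa-miR-15a-5p to -0.052, hsa-miR-15b-5p to -0.11, hsa-miR-7-5p to -0.17, hsa-miR-6165 to 0.0075, the median of the miR-15/16 family to -0.052 and the median of the GC-rich array miRNAs to 0.078. With labelling spike-in scaling hsa-let-7c-5p turned to -0.062, hsa-miR-15a-5p to -0.018, hsa-miR-15b-5p to -0.085, hsa-miR-24-3p to -0.021, hsa-miR-7-5p to -0.049, hsa-miR-494-3p to 0.21, the median of the list of hsa-miR-17-5p and its paralogs to -0.039 and the median of the miR-15/16 family to -0.018. With quantile normalization hsa-miR-19b-3p turned to 0.034, hsa-miR-16-5p to -0.018 and hsa-miR-7977 to -0.019. With the series value table hsa-miR-19b-3p turned to 0.082 and hsa-miR-15b-5p to -0.028. With the total gene signal of the scanner file hsa-miR-19b-3p turned to 0.091 and hsa-miR-15b-5p to -0.019. With all probes of the miRNA hsa-miR-19b-3p turned to 0.27. With no filter on dim probes hsa-miR-19b-3p turned to 0.27. With both arrays that stand apart left out hsa-miR-19b-3p turned to 0.70, hsa-miR-181b-5p to -0.43, hsa-miR-494-3p to 0.30, hsa-miR-7975 to -0.32, hsa-miR-7977 to -0.35, hsa-let-7a-5p to 0.18, hsa-miR-5100 to -0.27, the median of the let-7 family to 0.12 and the median of the miRNA entries overlapping other abundant RNAs to -0.30. With both arrays left out with the probes of the 6-array comparison hsa-miR-19b-3p turned to 0.34, hsa-miR-181b-5p to -0.28, hsa-miR-494-3p to 0.45, hsa-miR-7975 to -0.17, hsa-miR-7977 to -0.20, hsa-let-7a-5p to 0.34, hsa-miR-5100 to -0.12, the median of the let-7 family to 0.29 and the median of the miRNA entries overlapping other abundant RNAs to -0.17. With array quality weights hsa-miR-19b-3p turned to 0.28, hsa-miR-181b-5p to -0.20, hsa-miR-494-3p to 0.39, hsa-miR-7975 to -0.11, hsa-miR-7977 to -0.12, hsa-let-7a-5p to 0.27, hsa-miR-5100 to -0.044, the median of the let-7 family to 0.26 and the median of the miRNA entries overlapping other abundant RNAs to -0.11. With normexp background correction hsa-miR-15b-5p turned to -0.00112 and hsa-miR-494-3p to 0.11. With the brightest probe only hsa-miR-15b-5p turned to -0.28. With the 75th percentile over all probes hsa-miR-494-3p turned to 0.11. With no scaling hsa-miR-494-3p turned to 0.11. Over the comparisons without single arrays, the ranges that held both signs were -0.048 to 0.26 for hsa-let-7c-5p, -0.27 to 0.35 for hsa-miR-19b-3p, -0.059 to 0.91 for hsa-miR-34a-5p, -0.33 to 0.61 for hsa-miR-15a-5p, -0.23 to 0.43 for hsa-miR-15b-5p, -0.36 to 0.58 for hsa-miR-181b-5p, -0.24 to 0.50 for hsa-miR-7-5p, -0.57 to 0.59 for hsa-miR-494-3p, -0.15 to 0.47 for hsa-miR-7975, -0.30 to 0.19 for hsa-let-7a-5p, -0.31 to 0.23 for the median of the let-7 family, -0.048 to 0.34 for the median of the list of hsa-miR-17-5p and its paralogs, -0.10 to 0.43 for the median of the miR-15/16 family and -0.064 to 0.52 for the median of the curcumin miRNAs of earlier reports.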

Other observations

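The 4-array comparison, also with the probes of the 6-array comparison, the difference between arms per array and the count of splits for single miRNAs were chosen only after the result was seen. With DMSO replicate 2 and curcumin replicate 1 left out, 66 of 164 miRNAs passed limma's test at an adjusted p under 0.05 (82 had an unadjusted p under 0.05). The kept pairs differed with SDs of 0.25 and 0.19 log2 units, against deviations of 0.79 and 0.86 for the arrays left out. Arrays were thus kept for their agreement, so SEs and p-values here are likely too small. Below, rose and fell name only the sign of calls in these 4 arrays. Of the 10 miRNAs formed by the 5 of smallest p in each direction over all 6 arrays, 8 passed, and hsa-miR-1260b and hsa-miR-130b-3p did not. With the probes and scaling of the 6-array comparison hsa-miR-1260b did pass, at 0.46 (limma adjusted p = 0.0211). In these 4 arrays all 3 members of the miR-29 family rose, hsa-miR-29b-3p by 1.33 ± 0.31 (SE), hsa-miR-29a-3p by 0.91 ± 0.13 and hsa-miR-29c-3p by 0.73 ± 0.11. hsa-miR-23a-3p rose by 1.02 ± 0.10 and hsa-miR-23b-3p by 0.84 ± 0.08, and 3 of 5 miR-30 miRNAs rose (hsa-miR-30a-5p by 0.91 ± 0.13). Of these miR-30 miRNAs, hsa-miR-30b-5p and hsa-miR-30c-5p lay at the floor on both DMSO arrays and were not tested over 6 arrays. Their p-values therefore rest partly on the floor. hsa-miR-25-3p and hsa-miR-19a-3p rose by 0.67 ± 0.13 and 0.62 ± 0.09 (0.82 ± 0.12 and 1.1 ± 0.12 with the probes and scaling of the 6-array comparison). Against this, hsa-miR-210-3p fell by 0.68 ± 0.11, hsa-miR-125a-3p by 0.89 ± 0.11 and hsa-miR-21-3p by 0.80 ± 0.18. Of 13 GC-rich array miRNAs 10 fell and 0 rose (camera adjusted p = 0.000185, unadjusted p = 0.0480 with an estimated correlation and adjusted p = 0.580). Among those that fell, hsa-miR-6088 and hsa-miR-3196 lay at the floor on both curcumin arrays. With the probes and scaling of the 6-array comparison hsa-miR-4281, hsa-miR-1202 and hsa-miR-6085 did not pass (limma adjusted p = 0.0577, 0.0732 and 0.243). The 4 arrays are part of the 6, so that like signs in both comparisons are no independent evidence. The signs of 2 calls, hsa-miR-19b-3p and hsa-miR-181b-5p, differed between them.

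The detection rule and the scaling were applied anew to the 4 arrays, which changed the probes of 10 miRNAs tested in both comparisons, 5 of them among the 66. With the probes, scaling and floor of the 6-array comparison, 62 of 138 miRNAs passed (38 higher, 24 lower, 76 at an unadjusted p under 0.05), 47 of them among the 66. The numbers higher and lower therefore depend on this choice. hsa-miR-19b-3p stood at 0.70 ± 0.07 with an added probe and at 0.34 ± 0.12 with the probe and scaling of the 6-array comparison (limma adjusted p = 0.0562). hsa-let-7b-5p, hsa-let-7e-5p, hsa-miR-378a-3p and hsa-miR-181b-5p passed as lower in the 4-array comparison with its own probes and scaling (-0.36, -0.28, -0.54 and -0.43) but not with those of the 6-array comparison (-0.21, -0.13, -0.39 and -0.28). The probes of these miRNAs did not change, so the scaling moved their values. hsa-miR-23a-3p, also on unchanged probes, stood at 1.02 with the new scaling and at 1.17 with that of the 6-array comparison.

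The 38 miRNAs that were lower over the 4 arrays had a median probe GC content of 70.3% and the 28 that were higher one of 50%, against 54.8% for all. Probe GC content as the whole cause is argued against, though not as a part: after removal of each array's GC trend 50 miRNAs still passed (22 higher, 28 lower), 39 of them among the 66, and the median absolute log2 fold change of the 66 went from 0.66 to 0.49. The choice of the closest arrays was simulated: of 100 data sets without a group effect but with the arrays' main axis of spread, 0 gave as many calls (at most 50, with any call in 21), which rests on an assumed profile and excludes nothing. Slide and scan cannot be told apart from curcumin, since 0 slides held both groups. The 4 arrays allow 3 splits into pairs, too few for a share under 0.05: the real split gave 66 calls, 1 split in all reached that number, and the highest of the others gave 0. The arrays kept were the closest pair of each group. Every other split parts these pairs and puts the difference between them into the spread. The choice of arrays thus favoured the real split, and this count tests nothing.

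Over all 6 arrays, 10 splits into 3 and 3 are possible, too few for a share under 0.05. The real split gave 10 miRNAs at an unadjusted p under 0.05, 4 of the 10 splits gave as many, and the highest of the others gave 32, with DMSO replicates 1 and 3 and curcumin replicate 3 on one side. The 3 splits that set DMSO replicates 1 and 3 with 1 curcumin array gave 14, 20 and 32, which points to a structure of the arrays in which DMSO replicate 2 lies apart. A wrong label on that array was not separated from other sources of this structure. For lists past the threshold the real split gave 0, so all 10 splits gave as many by construction and this count tests nothing. The highest of the others gave 9.

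miRNAs whose hairpins neighbour each other in the genome had like fold changes, which may come from neighbouring hairpins being one transcript. Of the 138 miRNAs, 132 matched a hairpin gene in the GRCh38.p14 table, and 39 pairs lay within 10 kb. Their log2 fold changes differed by 0.32 on average, against 0.51 for random pairs (permutation p = 0.0034, one-sided). Without pairs that share a family number, where probes of similar sequence may pick up both, the difference was 0.31 over 31 pairs (permutation p = 0.00552). Related miRNAs under different numbers, such as hsa-miR-17-5p and hsa-miR-20a-5p, stayed in, so signal shared between similar sequences was not excluded. The random pairs drew on all 132 matched miRNAs, of which 37 lay in pairs.

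The signal of a 5p probe cannot be set against that of a 3p probe, but their mean difference over the 8 hairpins with both arms tested can be compared between groups. It was 0.75 log2 units larger after curcumin, with an SD between arrays of 0.27 for DMSO and 0.14 for curcumin (n = 3 each, exact permutation p = 0.1, the smallest possible). The hairpins were picked by detection on all arrays of 1 group, which can favour a difference between the groups. The permutation does not account for this, and with detection on all 6 arrays 2 hairpins were left. The probes of the 5p arms had a mean GC content of 51.4% and those of the 3p arms 59.7%. After removal of the GC trend the difference between the groups was 0.63, and the fold change of the 5p arm was above that of the 3p arm in 7 of 8 hairpins.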
